A study of Mus musculus with 8 samples.

How the data were processed

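The 8 libraries were made from mRNA of the central amygdala of 129SV mice aged 7 months, per the labels. Of these, 4 libraries came from mice given a high fat diet for 20 weeks and 4 from mice on normal chow. Per the labels' protocols, RNA was extracted with Trizol from flash frozen tissue, poly(A) RNA was selected with oligo(dT) beads, fragmented and primed with random hexamers, and single-end reads were generated on a BGISEQ-500 instrument. The labels do not say that each library is a separate animal, so p-values measure only the spread between these samples, which may be technical.

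The authors deposited 1 table of estimated read counts per gene for each library, whose values need not be whole, and 35.2% of them differed from a whole number by more than 1e-06. Bowtie2 2.2.5, RSEM 1.2.8 and the mouse build mm10 are named in the submitters' processing notes, without a role or an order. The gene annotation and the strand setting are not given in the sources used here, so reads of overlapping and antisense genes cannot be told apart. The same table holds the authors' mean expected count, mean FPKM and mean TPM of each diet group, per the file headers. The deposited mean counts equalled the mean of the 4 libraries within 3.6e-12. The deposited FPKM means served only to derive an implied transcript length, and the deposited TPM means are printed as the authors' values, with no SD. Reads that the authors' counting divided among near-identical genes make the values of Hba-a2, Hspa1b, H2-K1, H2-D1 and the ribosomal protein genes uncertain. LOC115488023 was not checked for copies.

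The estimated counts were rounded to whole numbers. Totals per library were 17451111 to 19562368 counts over 18983 genes. Genes were kept by filterByExpr, which left 15186, and libraries were scaled by TMM factors. The diets were compared with edgeR 4.0.16 in R 4.3.3 by the two-sided quasi-likelihood test, with Benjamini-Hochberg adjusted p under 0.05 as the threshold and no covariate. The log2 fold change is high fat diet over chow, and its SE is the fold divided by the root of the F statistic. CPM values use TMM-scaled library sizes, and log2 CPM uses a prior count of 2. Entrez identifiers of 15151 of the 15186 tested genes matched RefSeq annotation of GRCm38.p6, the same build as mm10, from which coordinates were taken.

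Before the data were examined, 43 gene lists of cell types, pathways and technical classes were fixed, with 756 genes, of which 718 are in the table. Of these lists, 40 had at least 5 tested members. They were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation beside it, and with fry. A list score per library is the mean over members of log2 CPM minus the member's mean over the 8 libraries. Scores and library totals were compared by an exact permutation test over the 70 assignments of 8 libraries to 4 and 4, whose smallest p is 0.0286. The genes named were also set by a rule fixed at that time. It takes the 12 genes with the smallest p past the threshold in each direction, or the 6 with the smallest p as values where fewer than 6 pass. It takes up to 4 members of each list past the threshold, or the 2 with the smallest p as values. It adds Prkcd, Sst, Crh, Tac2, Nts, Pdyn and Penk, and Xist and Ddx3y as a check of the labels. Of the genes this rule takes, 1 is not reported here. Other genes are named as chosen after their values were seen.

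The edgeR test was tested on simulated data in which 200 of the 15186 genes, drawn at random, were changed. With the folds multiplied into the real counts, it called 34 of 67 genes changed 2-fold and 52 of 67 changed 4-fold. It called 66 of 66 changed 8-fold and 0 of the 14986 genes left as they were. That 0 does not measure false calls, since the real counts gave 0 calls before any fold was added. With counts drawn from the estimated dispersions, the edgeR test called 44.8%, 83.6% and 97.0% of genes changed 2-fold, 4-fold and 8-fold. There it made 10 calls among 14986 unchanged genes. The alternatives fixed at the start were RLE and upper-quartile factors, the title number as a block, leaving out each library, no filter beyond 1 count, a mean of at least 50 counts, DESeq2 1.42.0, limma-voom with and without sample quality weights, 1 surrogate variable from sva 3.50.0, an adjusted p under 0.1, and a log2 fold of at least 0.5. Leaving out chow replicates 5 and 8, the excitatory marker score as a covariate, the exact permutation test of list scores, the surrogate variable for lists and named genes, and an adjusted p under 0.1 in DESeq2 and limma-voom were added after seeing the data.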

Results

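The central amygdala, a forebrain nucleus involved in fear, feeding and autonomic control, was profiled by mRNA sequencing after 20 weeks of high fat diet or normal chow. Each diet had 4 libraries, named by the numbers 1, 2, 5 and 8 of their titles. Library totals were 18293134 ± 478626 counts with high fat diet and 18231801 ± 923783 with chow (SD, n = 4 each; exact permutation p = 0.886, two-sided). Genes with at least 10 counts numbered 15131 ± 167 and 15142 ± 45 (SD, n = 4 each; exact permutation p = 0.971). The closest pair of libraries was high fat replicate 5 and chow replicate 2, with a chi-square per degree of freedom of 8.12. Pairs within a diet ranged from 16.2 to 198, so no 2 libraries of a diet agreed within sampling noise.

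The libraries differed within the diets as well as between them. The first principal component held 49.2% of the variance, with chow replicate 1 at 97.6, chow replicates 5 and 8 at 8.58 and 8.35 and chow replicate 2 at -33.2. The 4 high fat libraries lay between -32.6 and -5.31. The second set chow replicates 5 and 8 apart at -49.0 and -44.5. Genes named here for single libraries were chosen after their values were seen. Ttr, the transthyretin gene of choroid plexus, was at 5794 CPM in chow replicate 1 and 71.5 CPM in chow replicate 5. Slc17a7, the vesicular glutamate transporter of cortical and basolateral excitatory neurons, was at 256, 200 and 81.8 CPM in chow replicates 1, 5 and 8. In chow replicate 2 it was at 1265 CPM, beside 557 to 1724 CPM in the 4 high fat libraries.

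**Figure D1:**
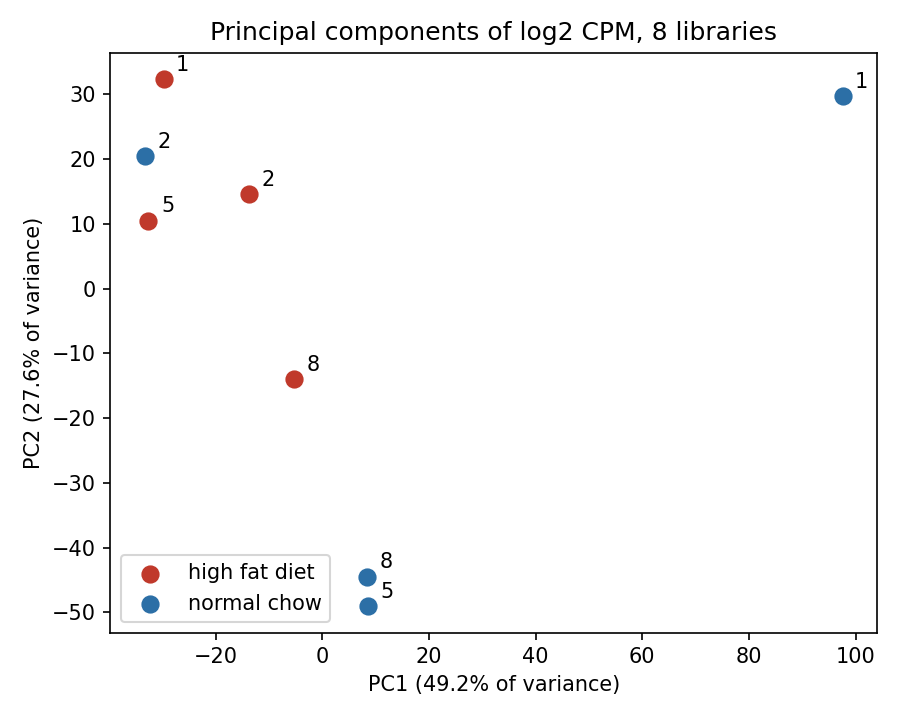
Principal components of log2 CPM over the tested genes, with PC1 on the horizontal axis and PC2 on the vertical axis. Each point is 1 library, coloured by diet and numbered by replicate. Chow replicate 1 lies at 97.6 on PC1, and chow replicates 5 and 8 lie at -49.0 and -44.5 on PC2.

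The main comparison asked which genes differ in the central amygdala between high fat diet and chow. No gene passed the threshold: edgeR called 0 of 15186 genes, 0 higher and 0 lower, with a smallest adjusted p of 0.753. At an unadjusted p under 0.05 there were 649 genes, 250 higher and 399 lower, where chance gives about 759 on average. Genes are not independent, and with 1 library left out this count ran from 131 (without high fat replicate 1) to 2972 (without chow replicate 2). A count under 759 therefore does not show that no gene changed. DESeq2 called 0 genes, with 990 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0722, and limma-voom called 0, with 652 and 0.771. Quality weights in limma-voom gave 0 genes, with 4492 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0675. At an adjusted p under 0.1 edgeR called 0 genes. At that threshold, applied to the other tools after seeing the data, limma-voom called 0, DESeq2 1 (Hvcn1) and limma-voom with quality weights 2775, 1455 higher and 1320 lower. The quality weights ran from 0.0865 for chow replicate 1 to 3.38 for high fat replicate 2. Chow replicate 2 had the next lowest weight, 0.421, and chow replicates 5 and 8 had 1.47 and 2.75, so chow rested mainly on these last libraries. The biological coefficient of variation was 29.3% and the median SE of a log2 fold change was 0.21. Without chow replicate 2, edgeR called 116 genes, 92 higher and 24 lower, while leaving out any other library gave 0.

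The genes with the smallest p are given as values that did not pass, each with adjusted p = 0.753 by edgeR. Those with positive folds included Igfbp3, an insulin-like growth factor binding protein (chromosome 11, 7206086 to 7215498, mm10), at 33.4 ± 4.73 CPM with high fat diet and 14.9 ± 7.38 CPM with chow (SD, n = 4 each). Cyp2e1, a cytochrome P450 (chromosome 7, 140763819 to 140774990), was at 1.36 ± 0.206 and 0.562 ± 0.130 CPM. Plagl1, an imprinted zinc finger gene (chromosome 10, 13090832 to 13131694), was at 94.4 ± 24.0 and 45.7 ± 12.5 CPM. Ppp1r14c, Pcdhac1 and LOC115488023 had log2 folds of 0.54 ± 0.13, 0.83 ± 0.22 and 1.23 ± 0.34 (SE). Those with negative folds included Hvcn1, a voltage-gated proton channel (chromosome 5, 122206805 to 122242297), at 3.41 ± 0.307 and 7.99 ± 2.38 CPM. Deptor, an inhibitor of mTOR (chromosome 15, 55112317 to 55259273), was at 20.8 ± 2.81 and 33.7 ± 6.87 CPM. Adm, the adrenomedullin gene, Bfsp1 and Lrrc38 had log2 folds of -1.27 ± 0.34, -1.16 ± 0.30 and -1.75 ± 0.44. Tnnt1, a troponin, had -3.62 ± 1.02, and its chow values ran from 1.05 CPM in replicate 2 to 35.5 CPM in replicate 5. Without chow replicate 2, Igfbp3, Hvcn1 and Deptor passed, with adjusted p of 0.0318, 0.0431 and 0.0494 by edgeR.

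Genes that mark central amygdala populations did not pass the test. Prkcd, the protein kinase C delta gene of a central lateral population, was at 16.3 ± 6.16 CPM with high fat diet and 94.3 ± 120 CPM with chow, where replicate 5 alone was at 273 CPM. Ramp3 and Zic1 of the thalamic list were also highest in that library, at 44.4 and 99.1 CPM, as were Shox2 and Tnnt1, at 33.0 and 35.5 CPM. Sst, Crh, Tac2, Nts, Pdyn and Penk, which encode neuropeptides, had log2 folds of 0.15 ± 0.23, -0.63 ± 0.61, -1.09 ± 0.71, -0.63 ± 0.49, -1.11 ± 0.80 and -1.42 ± 0.85 (SE). The authors' deposited mean TPM of Sst was 1549 with high fat diet and 1308 with chow. The fixed list of central amygdala neuron types was called lower by camera at adjusted p = 0.0320 (0.667 with an estimated correlation), with 14 of 20 members negative and a median log2 fold of -0.67. Meis2, a homeobox gene, had -1.05 ± 0.37 in it. Drd1, Drd2, Ppp1r1b, Tac1 and Penk are in both this list and the striatal list, which was called lower too. This list was not called by camera without high fat replicate 1, chow replicate 1 or chow replicate 8 (adjusted p = 0.348, 0.429 and 0.157), nor with upper-quartile factors (adjusted p = 0.0574). Without chow replicate 8 the folds of Sst and Crh were 0.032 and -0.13.

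At the preset correlation, camera called 20 of the 40 lists, 8 higher and 12 lower. With an estimated correlation it called 0, with a smallest p of 0.079 and a smallest adjusted p of 0.667, so each list call below was lost there. Over all lists, 0 members passed the threshold over all genes and 0 passed adjusted over the list alone. By fry 0 lists passed, with a smallest adjusted p of 0.597 for direction and 0.395 for change either way. The exact permutation test of list scores gave 0 lists, with a smallest p of 0.0857 and a smallest adjusted p of 0.572. Since its smallest possible p is 0.0286, a list could pass after adjustment only if many lists reached that value together. Without adjustment, 0 lists were under 0.05. Without chow replicate 1 camera called 12 lists, and without chow replicate 8 it called 13. With 1 surrogate variable as a covariate, a setting added for lists after seeing the data, it called 9 lists, and 12 of the 20 calls were lost. That variable was 0.90 in chow replicate 1 and between -0.26 and 0.011 in the other libraries, so it mainly set that library apart. Of the 20 lists, 13 lost their call without at least 1 of the 8 libraries, and 7 were called without each of them: the excitatory, striatal, thalamic, microglia, myelin, ribosomal and heat shock lists. Of these 7, the thalamic, myelin and heat shock lists lost their call with chow replicates 5 and 8 left out together, a choice made after seeing the data (adjusted p = 0.210, 0.891 and 0.210). Their mean log2 folds went from -1.21, -0.93 and 0.24 to -0.32, -0.38 and 0.12. In that setting the central amygdala, dopamine and opioid, unfolded protein, fatty acid synthesis, glutamate receptor and synaptic vesicle lists also lost their call (adjusted p = 0.286, 0.490, 0.344, 0.244, 0.203 and 0.412). The mean folds of the dopamine and opioid, unfolded protein, synaptic vesicle, ependymal and oxidative phosphorylation lists were -0.24, 0.0088, 0.083, -1.98 and -0.27 there. The myelin and ribosomal calls were lost with the surrogate variable (adjusted p = 0.0960 each).

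Lists of neurons from neighbouring regions went in opposite directions. The basolateral and cortical excitatory list was called higher (adjusted p = 2.31e-07; 0.667 with an estimated correlation), with 17 of 20 members positive and a median log2 fold of 0.81. Its score was 0.65 ± 0.38 with high fat diet and -0.65 ± 1.05 with chow (SD, n = 4 each; exact permutation p = 0.114), and chow replicate 2, at 0.92, lay among the high fat libraries. In it, Nptx1, a neuronal pentraxin, had 1.39 ± 0.56 and Emx2, a cortical homeobox gene, 0.76 ± 0.37. Without chow replicate 2 the mean log2 fold of the list went from 0.87 to 1.82, and Nptx1 was at 2.24 and passed (adjusted p = 0.0450 by edgeR). With chow replicates 5 and 8 left out together the mean fold of the list was 0.39 (adjusted p = 0.0207). The striatal spiny projection neuron list was called lower (adjusted p = 6.72e-06), with 17 of 19 members negative and a median of -1.41. Scn4b, a sodium channel subunit, and Pde10a, a striatal phosphodiesterase, had -2.12 ± 0.79 and -0.90 ± 0.34. The thalamic and habenular list was called lower (adjusted p = 5.85e-05), with 11 of 12 members negative and a mean log2 fold of -1.21, which was -0.77 without chow replicate 5. Ramp3, a receptor activity modifying protein, and Zic1 had -2.36 ± 0.73 and -1.54 ± 0.49, with the highest values of both in chow replicate 5, at 44.4 and 99.1 CPM. The medial amygdala and hypothalamic list (adjusted p = 0.579) and the GABAergic list (adjusted p = 0.865) were not called. Their examples Esr1, Lhx9, Kit and Nos1 had 0.73 ± 0.24, 1.54 ± 0.71, 1.25 ± 0.44 and 0.74 ± 0.29.

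**Figure D2:**
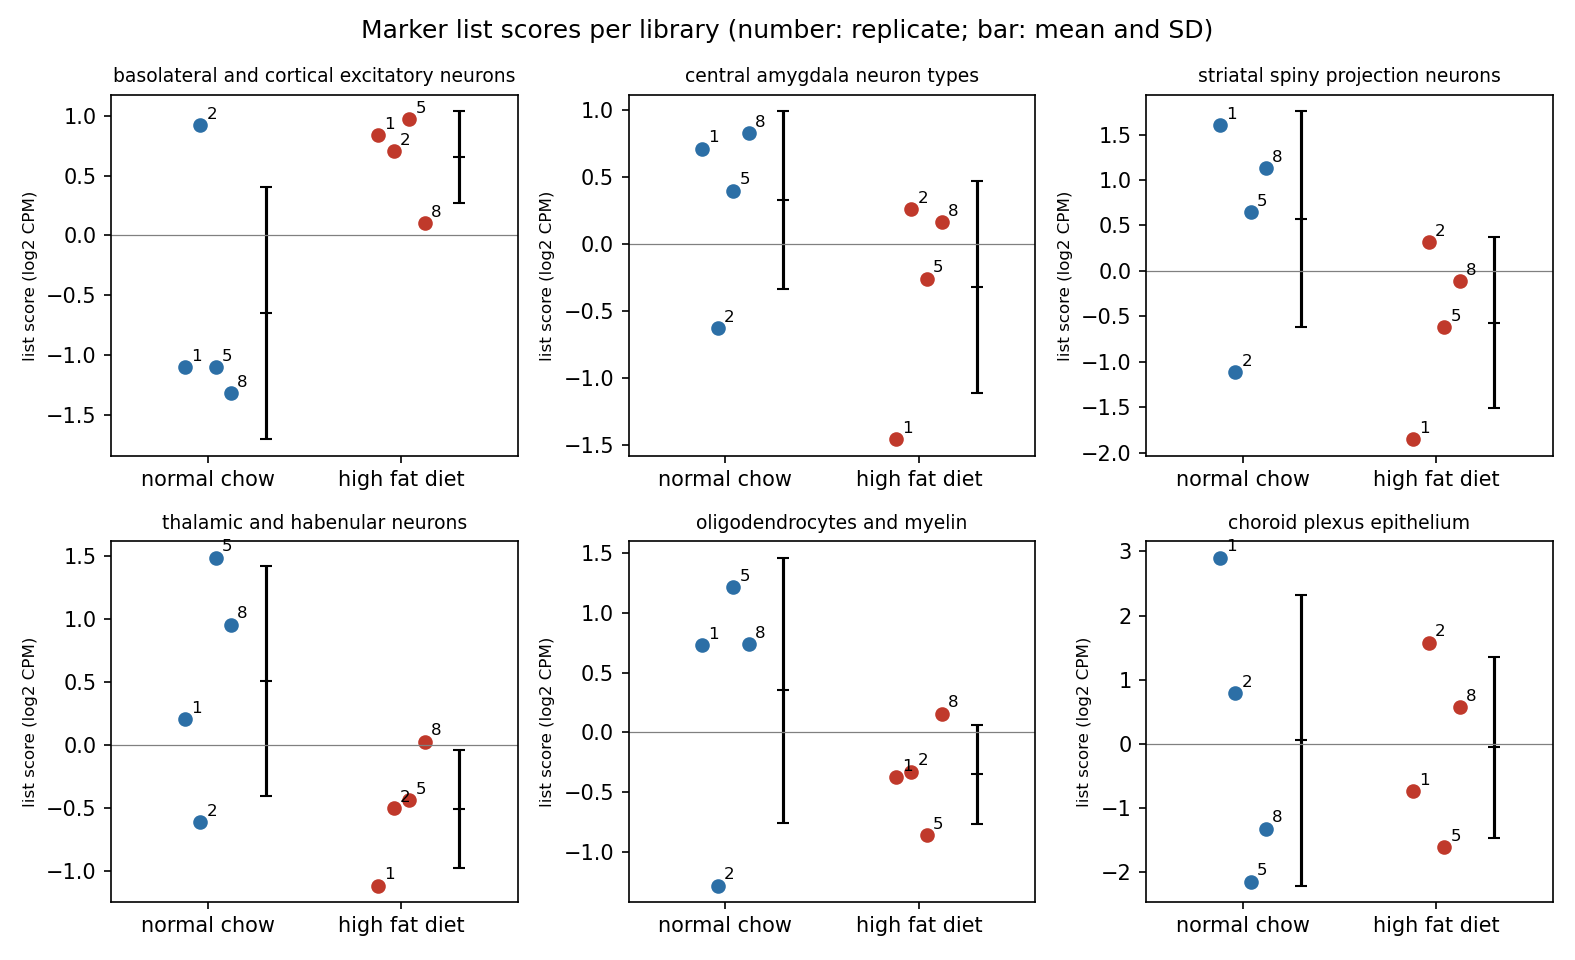
Scores of 6 marker lists per library, as the mean deviation of log2 CPM on the vertical axis, with the diets on the horizontal axis. Each point is 1 library numbered by replicate, and the black mark with its bar is the mean and SD of 4 libraries. In the excitatory panel, chow replicate 2 lies at 0.92 and the other 3 chow libraries lie between -1.32 and -1.11.

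Among the other cell types, oligodendrocyte and myelin genes were called lower (adjusted p = 5.85e-05), with 17 of 17 members negative and a median of -1.0. Opalin and Mog, both myelin proteins, had -1.23 ± 0.51 and -1.16 ± 0.48, and Mog passed without chow replicate 2 (adjusted p = 0.0467 by edgeR). Myelin scores of chow replicates were 0.73, -1.28, 1.22 and 0.74. Microglia and macrophage genes were called lower (adjusted p = 3.13e-05), with 18 of 19 members negative and a median of -0.40. Cd68, a lysosomal protein, and C1qb, a complement subunit, had -0.60 ± 0.25 and -0.61 ± 0.26. Ependymal genes were called lower (adjusted p = 0.0398), with 10 of 10 negative, and turned to the opposite direction without chow replicate 1 (mean log2 fold from -1.31 to 0.14, adjusted p = 0.687). They were not called without high fat replicate 5 or chow replicate 2 (adjusted p = 0.297 and 0.0598). The ependymal call was also lost with upper-quartile factors (adjusted p = 0.0714). Dynlrb2 and Foxj1, both of motile cilia, had -2.03 ± 0.91 and -1.60 ± 0.73, and -0.19 and -0.34 without chow replicate 1. Meningeal and perivascular fibroblast genes were called higher (adjusted p = 0.0442), with 8 of 12 positive, and Lum and Dcn, matrix proteoglycans, had 1.06 ± 0.41 and 1.52 ± 0.83. The fibroblast call was lost without high fat replicate 2 or 5 or chow replicate 5 or 8 (adjusted p = 0.0541, 0.128, 0.276 and 0.52), and its direction by camera turned with both of these chow libraries left out. The mean log2 fold of this list was 0.19, and 0.034, 0.0063 and -0.027 without high fat replicate 5, chow replicate 5 and chow replicate 8. It was 0.29 without high fat replicate 8 and 0.74 without chow replicate 2, where Dcn was at 3.09 and passed (adjusted p = 0.0481 by edgeR). The fibroblast call was also lost among genes with a mean of at least 50 counts (adjusted p = 0.0669). Astrocytes (0.471), oligodendrocyte precursors (0.276), endothelial cells (0.471), pericytes and smooth muscle (0.145), choroid plexus (0.732) and blood cells (0.136) were not called, by adjusted p. Their examples Aldh1l1, S100b, Sox10, Bcas1, Vwf and Itm2a had -0.27 ± 0.14, -0.49 ± 0.27, -0.95 ± 0.41, -1.06 ± 0.50, -0.46 ± 0.21 and -0.24 ± 0.14. Cnn1, Notch3, Otx2, Clic6, Hba-a2 and Alas2 had -0.72 ± 0.38, -0.38 ± 0.23, -2.02 ± 1.10, -2.12 ± 1.25, -1.44 ± 0.74 and -1.08 ± 0.56. Without chow replicate 1 the folds of Otx2, Clic6, Hba-a2 and Alas2 were 0.24, 0.37, -0.20 and -0.26.

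Heat shock, unfolded protein and immediate early lists were called higher, and interferon and oxidative stress lists lower. Cytosolic heat shock (adjusted p = 0.00577) had 10 of 12 members positive, with Hspa1b and Hsph1, both chaperones, at 1.29 ± 0.45 and 0.44 ± 0.18. Its scores in replicates 1, 2, 5 and 8 were 0.35, 0.27, -0.035 and -0.0093 with high fat diet. With chow they were -0.024, -0.027, -0.17 and -0.35. High fat replicates 5 and 8 thus lay near chow replicates 1 and 2, and in both diets replicates 1 and 2 scored above replicates 5 and 8. The unfolded protein and integrated stress response (adjusted p = 0.0136) had 16 of 20 positive, with Hspa5 and Pdia6, chaperones of the endoplasmic reticulum, at 0.50 ± 0.16 and 0.47 ± 0.16. Hspa5 was at 325 and 334 CPM in high fat replicates 1 and 2, 225 and 227 CPM in high fat replicates 5 and 8, and 188 to 207 CPM with chow. Immediate early genes (adjusted p = 0.0469) had 15 of 20 positive, with Fosl2 and Nr4a3 at 1.2 ± 0.57 and 1.25 ± 0.70. The unfolded protein call was lost without high fat replicate 1 or 2 or chow replicate 2 or 8 (adjusted p = 0.0955, 0.0541, 0.168 and 0.0866). Its mean log2 fold was 0.10, and 0.034, 0.15, 0.21 and 0.060 without high fat replicate 1, high fat replicate 8, chow replicate 1 and chow replicate 8. It was 0.053 with upper-quartile factors and 0.19 among genes with a mean of at least 50 counts. The immediate early call was lost without high fat replicate 2 or 5 or chow replicate 5 or 8 (adjusted p = 0.53, 0.128, 0.211 and 0.28), with RLE factors (0.0514) and among genes with a mean of at least 50 counts (0.0669). Its mean log2 fold of 0.29 was 0.17 without high fat replicate 2 and 0.51 without chow replicate 2. In the latter setting Nr4a3 was at 2.48 and passed (adjusted p = 0.0491 by edgeR). Interferon response genes were called lower (adjusted p = 5.85e-05), with 19 of 20 negative, and H2-K1 and H2-D1, class I histocompatibility genes, had -0.51 ± 0.18 and -0.52 ± 0.20. Oxidative stress and NRF2 targets were called lower (adjusted p = 0.00577), with 17 of 18 negative, and Gpx1 and Prdx1, peroxidases, had -0.68 ± 0.31 and -0.38 ± 0.19. Without chow replicate 1 the interferon and NRF2 lists were not called (adjusted p = 0.0681 and 0.370), with mean log2 folds from -0.49 to -0.15 and from -0.26 to -0.086. Cytokine genes (0.404) and glucocorticoid-responsive genes (0.175) were not called, by adjusted p. Ptgs2, Il33 and Arrdc2 had 1.49 ± 0.65, -0.90 ± 0.42 and -0.57 ± 0.24.

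Of the lists tied to diet and metabolism, fatty acid synthesis and lipid storage was called lower (adjusted p = 0.0398), with 16 of 21 negative. Its call was lost without high fat replicate 2, 5 or 8 or chow replicate 1, 5 or 8 (adjusted p = 0.0943, 0.128, 0.0514, 0.254, 0.0767 and 0.054). Lpl, lipoprotein lipase, had 0.86 ± 0.33 and Scd1, a fatty acid desaturase, -0.74 ± 0.30. Oxidative phosphorylation was called lower (adjusted p = 0.000344; 0.687 without chow replicate 1), with 35 of 35 negative and a median of -0.17, and Atp5j and Ndufs6 had -0.28 ± 0.17 and -0.32 ± 0.20. Ribosomal protein genes were called lower (adjusted p = 2.31e-07), with 30 of 30 negative and a median of -0.27, and Rpl23 and Rpl27 had -0.29 ± 0.15 and -0.34 ± 0.18. The mean log2 fold of the ribosomal list was -0.28, and -0.14 without chow replicate 1. In that library the list deviated by 0.54, and by 0.043 after removal of the trend with implied transcript length. For oxidative phosphorylation these deviations were 0.53 and 0.046, and the mean log2 fold went from -0.18 to -0.027 without that library. Fatty acid oxidation (0.113), cholesterol synthesis (0.471), insulin and mTOR signalling (0.158) and receptors for feeding signals (0.546) were not called, by adjusted p. Npy2r, a neuropeptide Y receptor, had 1.05 ± 0.32. Foxo1, Irs2, Insig1, Ehhadh and Ucp2 had 0.44 ± 0.18, 0.23 ± 0.15, -0.36 ± 0.15, -0.86 ± 0.37 and -1.57 ± 0.72. Ucp2 was at 283 CPM in chow replicate 1 and at 26.8 to 45.4 CPM in the other chow libraries, and its fold without chow replicate 1 was -0.21.

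Among neuronal signalling lists, dopamine and opioid signalling was called lower (adjusted p = 0.00577; 0.141 without chow replicate 1 and 0.113 without chow replicate 8), with 14 of 18 negative. Ppp1r1b and Adcy5, of the dopamine response, had -1.79 ± 0.78 and -0.65 ± 0.29, and both are in the striatal list too. Scores of the dopamine and opioid list and of the striatal list were both lowest in high fat replicate 1 and chow replicate 2, so these calls are not separate results. Ion channels (adjusted p = 0.00835), synaptic vesicle genes (adjusted p = 0.0379) and glutamate receptors (adjusted p = 0.0469) were called higher, with 21 of 31, 15 of 23 and 15 of 24 members positive. The channels and glutamate receptors were not called without chow replicate 1 (adjusted p = 0.679 and 0.362), with mean log2 folds from 0.14 to 0.0067 and from 0.20 to 0.099. In that library they deviated by -0.90 and -0.38, and by -0.13 and -0.14 after removal of the length trend. Without chow replicate 2 the mean folds of channels, synaptic vesicle genes and glutamate receptors were 0.31, 0.32 and 0.38. In that setting Kcnj6 was at 1.73 and passed (adjusted p = 0.0401 by edgeR). The channel fold was 0.088 without high fat replicate 1. The mean fold of the dopamine and opioid list was -0.59, and -0.93 and -0.32 without high fat replicate 8 and chow replicate 8. The glutamate receptor call was also lost without high fat replicate 1 or 5 or chow replicate 5 or 8 (adjusted p = 0.0546, 0.128, 0.0665 and 0.0765), with RLE factors (0.0514) and among genes with a mean of at least 50 counts (0.0558). The synaptic vesicle call was lost without high fat replicate 1 or 2 or chow replicate 8 (adjusted p = 0.141, 0.0517 and 0.157), and its mean fold of 0.15 was 0.081 and 0.088 without high fat replicate 1 and chow replicate 8. Kcnj6, Syn2, Syt2, Grik4 and Grm4 had 1.07 ± 0.45, 0.72 ± 0.31, -1.15 ± 0.52, 0.76 ± 0.23 and -0.90 ± 0.31. GABA receptors (0.533), serotonin receptors (0.193), stress peptides (0.546), circadian clock (0.546), the renin-angiotensin system (0.910) and extracellular matrix (0.319) were not called, by adjusted p. Gabrd, Gabra5, Htr4, Htr1a, Fkbp5 and Nr3c2 had -0.83 ± 0.32, 1.00 ± 0.44, 0.74 ± 0.32, 0.75 ± 0.35, 0.41 ± 0.18 and 0.78 ± 0.36. Cry1, Bhlhe41, Agtr1a, Ednra, Spp1 and Col6a3 had -0.37 ± 0.17, -0.44 ± 0.21, -0.81 ± 0.36, 0.69 ± 0.33, -1.04 ± 0.38 and -0.65 ± 0.27. In 7 lists the median, the mean and the test differed in sign, and 0 of these were called.

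As a check of the labels, the Y-linked genes Ddx3y, Kdm5d and Eif2s3y were counted in all 8 libraries, with log2 folds of -0.021 ± 0.37, 0.18 ± 0.26 and 0.24 ± 0.39. Ddx3y was lowest in chow replicate 1, at 22.4 CPM, and between 74.0 and 88.3 CPM in the other chow libraries. Xist was not analysed here. Of the list of nuclear long noncoding RNAs only Snhg11 was tested, at 0.23 ± 0.48, and mitochondrially encoded genes were not analysed here.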

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

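The tests of explanations in this part were chosen after the values were seen. Within each diet, 282 groups of 4 values were searched for a library far from the other 3, over totals, genes counted, list scores and named genes. A gap that large relative to the range was found in 11 groups, where chance gives about 14. The gap as a share of the range was 0.904 for the excitatory list in chow, where replicate 2 was at 0.92 and the nearest other at -1.11. It was 0.925 for fatty acid synthesis and lipid storage in chow, with replicate 2 low at -0.10. For the unfolded protein response in chow it was 0.878, with replicate 1 high at 0.18. In log2 CPM, chow replicate 1 was low for Kdm5d (0.943), Eif2s3y (0.942), Snhg11 (0.894) and Ddx3y (0.871). Snhg11 was at 8.89 there and at 11.33 in the nearest chow library. With high fat diet the gaps were 0.838 for Tnnt1, low in replicate 2, 0.839 for Eif2s3y and 0.942 for Cry1, both low in replicate 1, and 0.932 for Arrdc2, high in replicate 8.

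Chow replicate 1 stood apart from the other 7 libraries. Loss of long transcripts is argued against as the whole cause. After removal of the trend with implied transcript length, the striatal list in this library still deviated by 1.78, above the highest other library at 1.36, while the ribosomal list moved from 0.54 to 0.043. As a part of the pattern, loss of long transcripts stays open. The Spearman rho of deviation with length, across 14172 genes that are not independent replicates, was -0.478, the lowest of the 8. Chow replicate 2 reached 0.281, with the opposite sign. A straight line on log2 length held 17.9% of the variance of the deviations in chow replicate 1, and 3.71% in chow replicate 2, the next highest. A trend with length was thus present in chow replicate 1, but what caused it was not tested. Tissue from choroid plexus and striatum is a candidate source, since the median choroid plexus gene deviated by 3.70, against 2.15 in the highest other library, with Ttr at 5794 CPM. Drd1, Drd2, Ppp1r1b, Tac1 and Penk of the striatal list are also in the central amygdala list. No biological explanation was tested, because 1 library cannot be set against its own diet.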

How the results depend on the processing

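The edgeR alternatives fixed at the start called 0 genes each except without chow replicate 2, where 116 genes passed, 92 higher and 24 lower, so leaving out 1 library gave 0 to 116 genes. DESeq2 and limma-voom with and without quality weights were run on all 8 libraries and called 0 genes at an adjusted p under 0.05. At an adjusted p under 0.1, chosen for these tools after seeing the data, DESeq2 called 1 gene, limma-voom 0 and limma-voom with quality weights 2775, against 0 for edgeR. Leaving out chow replicates 5 and 8 and the excitatory score as a covariate gave 0 genes each in edgeR. Lists called by camera ranged from 12 to 21 with 1 library left out, with 12 without chow replicate 1 and 13 without chow replicate 8. The count was 0 with an estimated correlation, 0 by fry and 0 by the exact permutation test of list scores. That last test could pass a list after adjustment only if many lists reached its smallest p together. RLE factors, upper-quartile factors and a mean of at least 50 counts gave 18 lists each. Chosen after seeing the data, leaving out chow replicates 5 and 8 gave 13 lists, the excitatory marker score as a covariate gave 11 and 1 surrogate variable gave 9. Chow replicates 1, 5 and 8 were not left out together, because 1 chow library would remain. The labels do not say what the title number means. Deviations of same-numbered libraries correlated at 0.0132, -0.0425, 0.0353 and 0.389 for numbers 1, 2, 5 and 8, and 2 of 8 libraries correlated best with their own number, so the libraries were not treated as paired. Scores of 2 of 40 lists, the medial amygdala and hypothalamic and the endothelial, had the same order by number in both diets, where chance gives about 1.7. With the number as a block, 0 genes and 20 lists were called, with glucocorticoid-responsive genes called (adjusted p = 0.0401) and the central amygdala list not (0.0716), and Ddx3y turned to 0.12. Mean folds of the excitatory, fibroblast, ependymal, channel and synaptic vesicle lists were 1.32, 0.50, -0.63, 0.24 and 0.24 with the block. For named genes, 1814 values kept direction and side of the threshold, 8 passed it, all without chow replicate 2, and 52 changed sign. No gene passed in the main test, so keeping the side of the threshold only repeats the lack of calls. For the called lists, 233 kept direction and call, 69 lost the call and 18 changed direction.

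For the sign changes that follow, the cause was not tested. With the excitatory score as a covariate, camera turned the direction of these lists, given with their mean log2 folds, which kept their sign for microglia and ependymal cells: central amygdala neuron types 0.34, striatal spiny projection neurons 0.42, microglia and macrophages -0.026, oligodendrocytes and myelin 0.62, meningeal and perivascular fibroblasts -0.50, ependymal cells -0.089, cytosolic ribosomal proteins 0.028, activity-regulated immediate early genes -0.065, dopamine and opioid signalling 0.81, oxidative phosphorylation 0.033, ionotropic and metabotropic glutamate receptors -0.0602, voltage-gated and background ion channels -0.017, oxidative stress and NRF2 targets 0.058. Of the 20 calls without the covariate 2 kept direction and call there, unfolded protein (adjusted p = 0.00152) and heat shock (0.0144). The thalamic, interferon, fatty acid synthesis and synaptic vesicle calls were lost with no turn of direction (0.859, 0.112, 0.984 and 0.730). So was the excitatory call (0.984), a loss fixed in advance because the covariate is that list's own score. Of the 11 calls there, 6 were lists not called without the covariate and 3 were in the opposite direction. By camera these were myelin higher (adjusted p = 3.13e-25), fibroblasts lower (1.79e-06) and dopamine and opioid signalling higher (0.000671). Without the covariate the estimated correlations of these lists were 0.92, 0.52 and 0.42. The calls with the covariate used only the preset correlation of 0.01, so their p-values may be far too small. Log2 folds of Scn4b, Pde10a, S100b, C1qb, Opalin, Mog, Sox10, Bcas1, Itm2a were 0.72, 0.093, 0.30, 0.022, 0.53, 0.53, 0.38, 0.67, 0.0030 there. Log2 folds of Notch3, Hba-a2, Alas2, Ppp1r1b, Adcy5, Arrdc2, Il33, Scd1, Ehhadh were 0.17, 0.066, 0.0198, 0.34, 0.10, 0.094, 0.40, 0.012, 0.082 there. Log2 folds of Atp5j, Ndufs6, Syt2, Gpx1, Prdx1, Crh, Tac2, Nts, Pdyn were 0.014, 0.087, 0.25, 0.033, 0.083, 0.80, 0.89, 0.29, 0.82 there. Log2 folds of Penk, Ddx3y were 0.66, 0.0042 there. Without chow replicates 5 and 8, the lists of meningeal and perivascular fibroblasts (-0.33) and activity-regulated immediate early genes (0.057) turned in camera, with Sst at -0.16 and Ddx3y at 0.46. With 1 surrogate variable ependymal cells was at 0.26, oxidative phosphorylation was at 0.022, Otx2 was at 0.16, Clic6 was at 0.18, Hba-a2 was at 0.064, Kdm5d was at -0.10, Eif2s3y was at -0.15, Snhg11 was at -0.21, Ucp2 was at 0.019. With quality weights Otx2 was at 0.40, Clic6 was at 0.33, Snhg11 was at -0.0073. In limma-voom Ddx3y was at 0.14. With 1 library left out, and with the sign turned without chow replicate 1 for all but Ddx3y, folds ranged from -1.62 to 0.14 for the ependymal list, -2.60 to 0.24 for Otx2, -2.83 to 0.37 for Clic6, -0.049 to 0.28 for Kdm5d, -0.065 to 0.40 for Eif2s3y, -0.11 to 0.43 for Snhg11, -0.32 to 0.14 for Ddx3y. The mean fold of the fibroblast list ranged from -0.027 to 0.74 and was negative without chow replicate 8, though its direction by camera did not turn there. The difference in total counts ranged from -198897 to 504855, and in genes with at least 10 counts it was -11.8. At this depth, 34 of 67 randomly drawn genes changed 2-fold were recovered in the simulation, so changes of that size or smaller were often not detectable. Genes with a wide spread did not pass at larger folds either, such as Prkcd at -2.54 ± 0.81 and Tnnt1 at -3.62 ± 1.02 (log2 fold, SE). The simulated shares therefore do not hold for such genes.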

Other observations

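The tests of explanations in this part were chosen after the values were seen, as were the genes named. Markers of other nearby nuclei varied between libraries of 1 diet. Chat, the acetylcholine synthesis gene, was at 21.9, 29.6 and 36.6 CPM in chow replicates 1, 5 and 8 and at 1.32 CPM in chow replicate 2. Lhx8, a cholinergic transcription factor, was at 17.1, 15.7 and 24.3 CPM in the same 3 libraries and at 0.607 CPM in chow replicate 2. Pmch, the melanin-concentrating hormone gene of the lateral hypothalamus, was at 0.336, 0.605, 52.2 and 77.9 CPM in high fat replicates 1, 2, 5 and 8, and at 0.621, 1.05, 55.5 and 23.6 CPM in the chow replicates of the same numbers. Hcrt, the hypocretin gene, was at 0.0560, 0.110, 9.74 and 31.6 CPM and at 0.0517, 0.276, 5.45 and 4.31 CPM. Both were low in replicates 1 and 2 and high in replicates 5 and 8 of both diets. The labels do not say what the number means.

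Marker lists differed between the diets at the preset correlation. RNA of chow replicate 1 stays open as a cause for the called lists whose mean fold shrank without that library. The folds of the unfolded protein, fibroblast, heat shock, thalamic and immediate early lists did not shrink. They were 2.13, 1.43, 1.25, 1.09 and 1.09 of their size, which argues against that library as the source of these folds. Over whole libraries without chow replicate 1, 0 of the 20 passed the exact permutation test of list scores. The smallest p was 0.0857, where 0.0286 was possible. With all 8 libraries 0 lists passed as well, at the same smallest p, so this test cannot decide. Camera still called 11 of the 20 lists without chow replicate 1. At the preset correlation it called a median of 13 lists over the other splits of the libraries, so these calls do not argue against that library as a cause. Mean folds of the excitatory, striatal, thalamic and myelin lists were 0.812, 0.691, 1.09 and 0.933 of their size without that library. They fell to under 0.5 of their size in 5 lists, the ependymal (-1.31 to 0.14), interferon (-0.49 to -0.15), oxidative phosphorylation (-0.18 to -0.027), ion channel (0.14 to 0.0067) and NRF2 (-0.26 to -0.086) lists. Heat shock and unfolded protein genes went from 0.24 to 0.30 and from 0.10 to 0.21, and ribosomal genes from -0.28 to -0.14. The central amygdala, dopamine and opioid, and fatty acid synthesis lists lost their call with folds of 0.804, 0.754 and 0.770 of their size, and glutamate receptors with 0.503. Regions sampled in different proportions may account for the differences: across 15166 genes outside the excitatory list, which are not independent replicates, the diet difference followed the slope on the excitatory score within diets at r = 0.816. Permuting the scores within diets gave an exact p of 0.0938. In the high fat libraries alone r was 0.558 (exact permutation p = 0.0833), and in the chow libraries alone it was 0.811 (p = 0.167). Each of these tests within a diet had only 24 orders. Chow replicates 1, 5 and 8 had near-equal scores (-1.11, -1.11 and -1.32), and orders that exchange them give nearly the same r. The chow test could thus hardly reach a small p, whatever the cause. The explanation by regions stays open, and the diet itself cannot be told apart from it. The smallest exact permutation p among the called lists over all 8 libraries was 0.0857.

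Without chow replicate 2, 116 genes passed the edgeR test, with the smallest p for Pcdh20, Neurod2, Bhlhe22 and Itga8, and 8 of the 20 excitatory list members were among the 92 higher genes. This library was the chow library with the highest excitatory score, at 0.92, so that count does not bear on the cause. A candidate explanation is again the regions sampled. Of 108 genes outside the list, 104 (96.3%) had a slope on the excitatory score within the high fat libraries of the same sign as their fold, against 69.0% of the other genes. Over the 24 orders of the scores the exact permutation p was 0.125, so the explanation stays open, as does an effect of diet that chow replicate 2 does not share, which was not tested.

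The count of called genes was 0, so 35 of 35 splits of the 8 libraries into 4 and 4 had to give as many, which says nothing about chance. The highest other split gave 1175 genes. That split set high fat replicates 1, 2 and 5 with chow replicate 2 against the other 4 libraries. Excitatory scores were 0.70 to 0.97 in the first set and -1.32 to 0.10 in the second. The split was picked for its count, and only 3 splits called any gene. A structure of the samples that crosses the diets is a candidate reading, which was not tested. For lists chance cannot be excluded: 4 of 35 splits gave as many as the 20 called, the highest other split gave 23, and the median over the other splits was 13.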
